A study of Mus musculus with 2 samples.

How the data were processed

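The study profiled trimethylation of lysine 4 of histone H3 (H3K4me3), a histone mark that in mammals lies over the start of active and poised genes, by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse neural progenitor cells from adult animals. Per the labels' protocols, the cells were grown in N2 medium with the growth factors EGF and bFGF, and sonicated chromatin was pulled down with an antibody. The libraries were amplified by PCR, made into single-stranded circles and read as DNA nanoballs. The labels give 2 samples, 1 H3K4me3 library marked "con" and 1 input library of chromatin that was not pulled down. The meaning of "con" is not given in the labels, and the file header names the H3K4me3 library after EGF instead. The labels were followed, and the values describe cells grown with EGF and bFGF, as the labels give for both samples. The file analysed is the peak list of the H3K4me3 library, and the input enters it as the background of the peak caller. The labels give no replicates, so no value carries an error between cultures, and no comparison between conditions was made.

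Per the submitters' processing notes, reads were placed on the mouse genome mm10; the aligner is not given in the sources used here. Per the file header, peaks were called with MACS 1.4.2 against the input with a p cutoff of 1e-05, a band width of 200 bp, a model fold of 10 to 30, an effective genome size of 1.87e+09 bp and a tag size of 25 bp, keeping at most 1 tag per position. The submitters' processing notes name MACS2 2.1.0 instead; the header and the layout of the columns are those of MACS 1.4.2. The file header gives 19147183 tags for H3K4me3, of which 18156769 were left after filtering, and 18441952 tags for the input, of which 17831241 were left. The larger library was scaled towards the smaller one, per the file header.

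The deposited file gives for each peak its position, length and summit in base pairs, its tag count, a score of 10 times the negative log10 of the p-value, the fold enrichment over the input as a ratio, and a false discovery rate in percent. The tag counts are not normalized, per the file header and the values, which are whole numbers. Fold enrichment, score and percent false discovery rate are the authors' own values per peak and were used here to describe, rank or filter peaks within the list. Peaks were called on 1 library, not on pooled samples. Keeping 1 tag per position limits the counts in the strongest peaks, and a weak site below the p cutoff is not listed, so a gene without a peak is a gene without a called peak at this depth. The weakest listed peak held 13 tags.

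Positions were joined to a RefSeq gene table of GRCm38.p6, the assembly that mm10 names, on chromosomes 1 to 19, X and Y. As a check of the build, all peaks were moved by 100 kb: the share at a gene end fell from 65.2% to 18.2%. The table gives a start and an end per gene, with no strand, transcript positions or sequence, so the planned windows around start sites and the planned matching on CpG content could not be used. A peak was instead counted at a gene when it overlapped, by at least 1 bp, the window of 1 kb either side of either end of the gene. One of these ends is the annotated start. Start sites inside a gene are missed by this rule, so a peak anywhere from 1 kb before to 1 kb after the gene was used as an alternative. A peak between close neighbours counted for each of them, and a region counted at a gene can lie beside the gene without overlapping it.

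Random expectation came from 100 random placements of the peaks on their own chromosomes, between the outermost genes or peaks; assembly gaps were not excluded. Before the data were examined, 21 gene lists were fixed. The share of a list's members with a peak was set against 10000 random lists of the same size drawn from the other protein-coding genes, not matched on any property, and a list was called above or below when it lay outside the central 95% of these. Chance would put 1.05 of the 21 lists outside. These percentiles describe this library; genes are not replicates, and no p-value was computed. Some genes are in more than 1 list (Egfr, Fgfr1, Fgfr3, Lhx2 and 2 Hox genes). Intervals are exact (Clopper-Pearson) 95% binomial intervals over genes or peaks and cover counting error only; PCR reads without molecular identifiers are not independent molecules. For widths, peaks 1 kb or less apart were joined, and the widest 5% of joined regions at an end of a protein-coding gene were called broad; a list's members with a peak were compared with random lists of genes with a peak.

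The rule for the genes named was fixed at the same point: the 10 protein-coding genes under the widest regions, the 5 with the highest fold enrichment, in each list the 2 members with a peak under the widest regions and the first 2 members without one, Actb and Gapdh, and the 3 distal peaks with the highest fold enrichment. For lists of over 30 members, members without a peak were not named. Some genes that the rule takes are not reported here. Any other gene is said to have been chosen after its values were seen. The overlap and list code was tested on simulated data. Of 10000 protein-coding genes given a peak centred on an end, 100% were recovered, and 9.09% of the other genes were also marked through a neighbour. Of 200 lists of 20 random genes 2% fell outside the central range, and 100% of 200 lists with 18 of 20 members marked were called above. Recovery was certain with peaks placed on the ends, so it checks the code and says nothing of real peaks that lie off an end. The alternatives were a stricter p (-log10 p of at least 10), a fold enrichment of at least 5, windows of 500 and 2500 bp, the summit in place of the overlap, other gaps and widths, other distances, curated genes, matching on gene density and peaks at 1 coding gene only. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used.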

Results

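To map the distribution of H3K4me3 in neural progenitor cells, 1 H3K4me3 library was sequenced and set against 1 input library of the same cell type. The cells came from adult mice and grew with EGF and bFGF, the growth factors that keep neural progenitors dividing in culture. After filtering, the H3K4me3 library held 18156769 tags and the input 17831241. With 1 library of each kind, the values below describe these cells without an error between cultures.

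The authors' list held 19265 H3K4me3 peaks, which covered 36.0 Mb or 1.93% of the effective genome size. The tag counts of the peaks summed to 26.5% of the filtered tags. Peaks had a median length of 1705 bp with quartiles of 1011 and 2400 bp, and a median of 198 tags. Their median fold enrichment over the input was 27.97, with quartiles of 10.9 and 41.4. Both reference genes were marked. Gapdh, which encodes a glycolytic enzyme, lay under a region of 5913 bp (mm10 chromosome 6) with a fold enrichment of 65.8, and Actb, which encodes cytoplasmic actin, under 4895 bp (chromosome 5) with 50.6. The peak at Gapdh also lay at an end of Iffo1 and Ncapd2.

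Most H3K4me3 lay at the ends of genes. Of 19261 peaks on the assembled chromosomes, 12552 overlapped the window of 1 kb around an end of an annotated gene, which is 65.2% (95% interval 64.5 to 65.8), and these held 85.8% of the tags in peaks. Random placements put 11.3% of peaks there, with a range of 10.7% to 11.99% over 100 placements. Peaks at gene ends were longer and stronger, with a median length of 2037 bp and a median fold enrichment of 36.9 (quartiles 24.5 and 44.8), than distal peaks, which had medians of 959 bp and 9.75 (quartiles 7.52 and 15.2). At 4337 protein-coding genes over 10 kb long with a peak at 1 isolated end, the summit lay inside the gene in 92.3% (95% interval 91.4 to 93.0), at a median of 324 bp from the end, and the peak reached 1451 bp into the gene and 602 bp out of it as medians. The share at gene ends moved with the window and the p threshold, from 59.5% with the summit in the window to 72.5% with a -log10 p of at least 10.

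**Figure D1:**
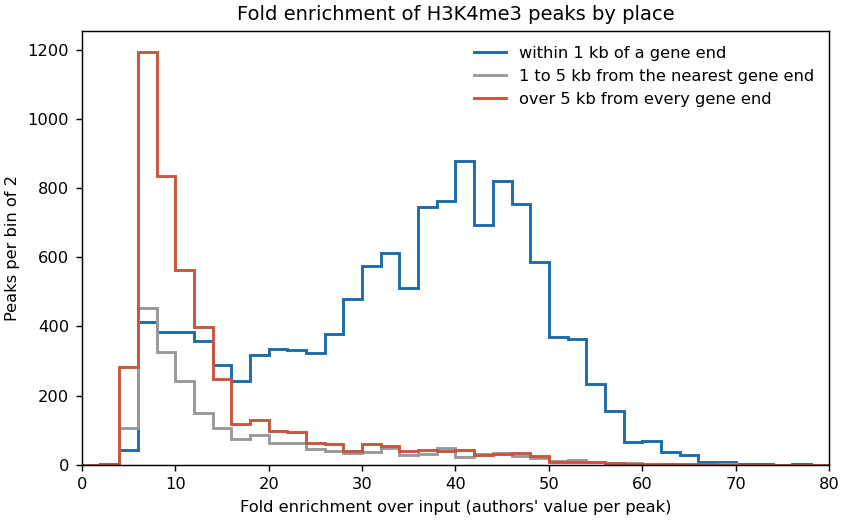
Number of peaks (vertical axis) by the authors' fold enrichment over the input in bins of 2 (horizontal axis), as outlines for peaks within 1 kb of a gene end, between these, and over 5 kb from every gene end. Peaks at gene ends had a median of 36.9 and distal peaks a median of 9.75.

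Protein-coding genes carried the mark far more often than other kinds of gene, apart from tRNA genes. A peak lay at an end of 12328 of 21887 protein-coding genes, which is 56.3% (95% interval 55.7 to 57.0), against 5.52% of genes with random placements and 11.2% with all peaks moved by 100 kb. The peak lay at 1 end only in 90.2% of these genes and at both ends in 1208. A further 1134 genes had a peak inside the gene and at neither end, so that 61.5% had a peak somewhere over the gene. Among 12727 long non-coding RNA genes, 20.3% had a peak at an end, and among 1228 microRNA genes 15.9%, against 7.27% and 5.21% with moved peaks. Without peaks at coding gene ends these shares were 8.24% and 5.86%. Pseudogenes had a peak in 1.93%, below the 3.80% found with moved peaks. Of 408 tRNA genes, 55.4% had a peak (95% interval 50.4 to 60.3), against 11.8% with moved peaks, and 40.4% had one without peaks at coding gene ends. In 27.4% of the marked protein-coding genes each peak was shared with an end of another coding gene, so the mark cannot be given to 1 of the neighbours.

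Genes of the progenitor state were marked almost without exception. Of 20 neural stem and progenitor genes, 18 had a peak at an end (90.0%, 95% interval 68.3 to 98.8), above 99.9% of random lists, whose median was 55.0%. Sox2, a transcription factor of neural and pluripotent stem cells, lay under a region of 12.1 kb with 1900 tags, and Hes1, a repressor downstream of Notch, under 8.09 kb with 1414 tags. The members without a peak at an end were Pax6 and Msi1, and each had a strong peak inside the gene, with a fold enrichment of 31.8 at Pax6 and 52.1 at Msi1. All 28 genes of EGF and FGF receptor to MAPK signalling, all 21 cell cycle genes and all 18 immediate early genes had a peak, above each of the 10000 random lists. Some of these peaks were shared with a neighbour. With only peaks at ends of 1 coding gene, 25 of the 28, 16 of the 21 and 16 of the 18 had a peak. These 3 lists stayed above the central range. Dusp4, a MAPK phosphatase, lay under 12.2 kb, and Spry4, a feedback inhibitor of receptor tyrosine kinases, under 11.3 kb, with a peak shared with an end of Arhgap26. Among the cell cycle genes, Ccnd1 and Ccnd2, which encode D-type cyclins, lay under 11.7 kb and 4.80 kb. Among the immediate early genes, Fosl2, an AP-1 subunit, lay under 7.04 kb and Myc under 6.47 kb. Genes linked to quiescence of neural stem cells had a peak in 12 of 15 (80%), inside the central range of random lists. Cdkn1b, an inhibitor of cyclin-dependent kinases, lay under 14.4 kb and Id2 under 9.06 kb, while Bmp4 and Hopx had peaks inside the gene and none at an end, with fold enrichments of 7.23 and 27.5. This list passed the upper bound when a peak anywhere over the gene was counted (14 of 15) and with windows of 2500 bp (13 of 15). It also did so with only peaks at ends of 1 coding gene, where its own count stayed at 12 of 15. The count fell to 10 of 15 with a -log10 p of at least 10 and with the summit in place of the overlap. Under both of these settings the quiescence list lay inside the central range, at the 80.5 and 88.0 percentiles.

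Genes used by nearly all cells were likewise marked. All 77 cytosolic ribosomal protein genes had a peak at an end, with the widest regions at Rpl35 (6.16 kb) and Rpl18 (5.66 kb), and 69 of 77 oxidative phosphorylation genes did (89.6%), with the widest region (8.01 kb) at an end of Atp5b. That region lay beside the gene and not over it, and the strongest peak of Atp5b (fold enrichment 42.7) lay at its other end. Of 22 genes for H3K4 methylation and Polycomb enzymes, 20 had a peak at an end. Setd1b and Kmt2a, which encode H3K4 methyltransferases, lay under 9.66 kb and 4.94 kb. The peak at Setd1b was shared with an end of Rhof and lay mostly beside Setd1b. Ash2l and Dpy30, which encode subunits of H3K4 methyltransferase complexes, had a peak inside the gene. These lists lay above at least 99.9% of random lists. With only peaks at ends of 1 coding gene, 37 of the 77 oxidative phosphorylation genes and 13 of the 22 enzyme genes had a peak, and both lists fell inside the central range. Of the 77 ribosomal protein genes 53 had such a peak, and that list stayed above.

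Genes of other germ layers and of the germline mostly had no called peak. Only 1 of 23 transcription factors of non-neural lineages had a peak at an end, a peak of 34 tags at Twist1, and Gata1 and Gata4, regulators of blood and heart, had none over the gene. Pax9, Runx1 and Tal1, named after their values were seen, had a peak inside the gene only, with fold enrichments of 8.68, 27.1 and 15.2. In the list of pluripotency and germline genes 1 of 18 had a peak (Tfcp2l1, fold enrichment 10.1), and Pou5f1 and Nanog had none. Of 18 genes of mature blood, liver, heart, pancreas and skin cells, 1 had a peak (Apoa1, fold enrichment 11.3), and Alb and Ttr had none. None of 1106 olfactory receptor genes had a peak (95% interval 0 to 0.333%). These 4 lists lay below at least 99.9% of random lists. Of the 39 Hox genes, which set position along the body axis, 9 had a peak (23.1%, 95% interval 11.1 to 39.3), below each of the random lists. The marked Hox genes were 8 of the 11 in the HoxA cluster and 1 of the 28 in the other clusters.

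Genes of differentiated brain cells were marked about as often as protein-coding genes in general. A peak lay at 10 of 20 neuronal genes, 7 of 14 astrocyte genes, 7 of 15 oligodendrocyte lineage genes and 6 of 10 ependymal genes, all inside the central range of random lists. Among neuronal genes Gad1, which encodes a GABA-synthesising enzyme, had a region of 3.12 kb and Eomes, a factor of intermediate progenitors, 2.84 kb; Dcx and Neurod2, a marker and a regulator of young neurons, had none. Among astrocyte genes the glutamate transporter gene Slc1a3 had 5.07 kb and the connexin gene Gja1 3.32 kb, whereas Gfap and Aqp4 had none. Among oligodendrocyte lineage genes Olig2, a factor of glial and progenitor cells, had 9.97 kb and Cnp 4.23 kb; Sox10 had none and Pdgfra had a peak inside the gene with a fold enrichment of 39.1. Among ependymal genes Cfap126 had 3.84 kb and Mia 1995 bp, the latter at a peak beside the gene and shared with an end of Rab4b, and Tmem212 and Ccdc153 had none. The joined region at Cfap126 held 308 tags. Its only peak at an end of that gene held 80 tags, with a fold enrichment of 8.62. The other marked ependymal genes, named after their values were seen, were Dynlrb2 (12.2), Tekt1 (16.6), Rsph1 (17.4) and Foxj1 (28.9).

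Markers of the other cell types that a brain culture could hold were marked less. Of 16 microglia and macrophage genes 4 had a peak at an end (25%, 95% interval 7.27 to 52.4), at the 0.57 percentile of random lists. The widest was at Cd68, at a peak shared with an end of Mpdu1; Aif1 and Itgam had none. Spi1 and P2ry12, named after their values were seen, had peaks of under 1 kb. Of 14 endothelial and mural genes 3 had a peak (21.4%, 95% interval 4.66 to 50.8), with Flt1 at 2.49 kb and Kdr at 1.24 kb, Pecam1 with a weak peak inside the gene (fold enrichment 8.68) and Cdh5 with none. Kcnj8, named after its values were seen, was the other marked member (967 bp). Neither list stayed below the central range with only peaks at ends of 1 coding gene, at the 9.99 percentile for microglia and the 7.41 for endothelium, and the endothelial list rose to 6 of 14 genes, at the 8.43 percentile, with a peak anywhere over the gene.

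Regulators of regional identity in the nervous system were split. Of 18 forebrain transcription factors 10 had a peak at an end. Six3, a factor of the anterior forebrain, lay under 12.7 kb and Meis2 under 8.20 kb, while Emx1 had no peak at an end and a weak one inside the gene (fold enrichment 5.52). Of 15 midbrain, hindbrain and spinal cord factors 7 had a peak, with En1 at 3.27 kb and Lbx1 at 1.99 kb. Their fold enrichments were 31.0 and 10.9. The other marked members, named after their values were seen, were En2 (8.68), Atoh1 (8.68), Tlx3 (10.1), Lmx1b (21.7) and Gbx2 (32.6). Pax5 had none and Pax2 had a peak inside the gene with a fold enrichment of at most 9.40. Both lists lay inside the central range. With the summit in place of the overlap, 4 of the 18 forebrain factors had a peak, and that list lay at the 0.915 percentile.

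**Figure D2:**
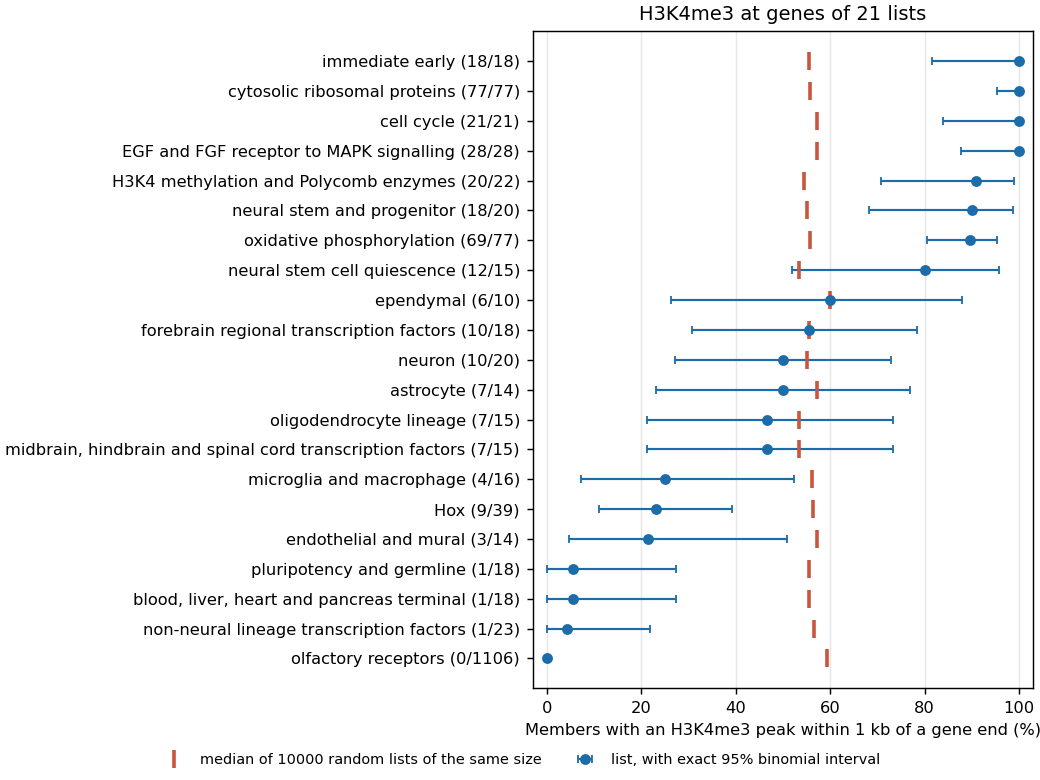
Share of each list's members with an H3K4me3 peak within 1 kb of a gene end (horizontal axis, percent) for the 21 lists (vertical axis, with the number of marked members and of members). Points carry exact 95% binomial intervals and vertical marks show the median of 10000 random lists of the same size; 7 lists lay above and 7 below the central range.

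Marked progenitor, quiescence, immediate early and signalling genes lay under broad H3K4me3 regions more often than marked coding genes in general. Joining gave 18264 regions, of which 10930 lay at a coding gene end with a median of 2150 bp, and the widest 5% were 546 regions of at least 4541 bp. The widest lay at Nr2f2, a nuclear receptor gene (25.4 kb, mm10 chromosome 7, 70341961 to 70367349). It was followed by Nfib, a nuclear factor I gene (24.3 kb, chromosome 4, 82494026 to 82518309), and by Pou3f2, a POU factor of neural progenitors (22.6 kb, chromosome 4, 22476867 to 22499420). The next were the neighbours Qk, an RNA-binding protein gene, and the predicted gene Gm46608 (16.5 kb), Frmd8 (16.1 kb), Bahcc1 (15.3 kb), Zeb2 (15.2 kb), Cdkn1b (14.4 kb) and Pou3f3 (13.9 kb). The region at Frmd8 lay mostly beside that gene and also covered an end of the long non-coding RNA gene Neat1. The strongest peak of Frmd8 (fold enrichment 44.8) lay at its other end, outside this region. Broad regions held 5.62% of all coding genes with a peak, but 10 of the 18 marked progenitor genes (55.6%, 95% interval 30.8 to 78.5), 6 of 12 marked quiescence genes (50%), 7 of 18 immediate early genes (38.9%) and 8 of 28 signalling genes (28.6%). Each of these 4 lists lay above the central range of random lists of marked genes, here and with peaks not joined, with a gap of 3 kb and with the widest 10%. Of 77 ribosomal protein genes 2 lay in broad regions (2.60%), as did 2 of 21 cell cycle genes (9.52%) and none of the 10 marked neuronal genes, inside the central range. The highest fold enrichments fell mostly on regions below the broad bound, at Nr1h2, the gene of a liver X receptor (77.4 over 2.07 kb), Anp32e (73.8), Chd6 (71.6), Tubb5, a tubulin gene in a broad region (70.9 over 7.66 kb), and Bap1, a deubiquitinase gene with a peak shared with an end of Phf7 (70.2). Other lists passed the upper bound under an alternative. These were ribosomal protein genes (14 of 77) and Hox genes (4 of 9) with a gap of 3 kb, oligodendrocyte lineage genes with peaks not joined and with the widest 10% (3 of 7 in each), and H3K4 methylation and Polycomb enzyme genes with peaks not joined (4 of 20).

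**Figure D3:**
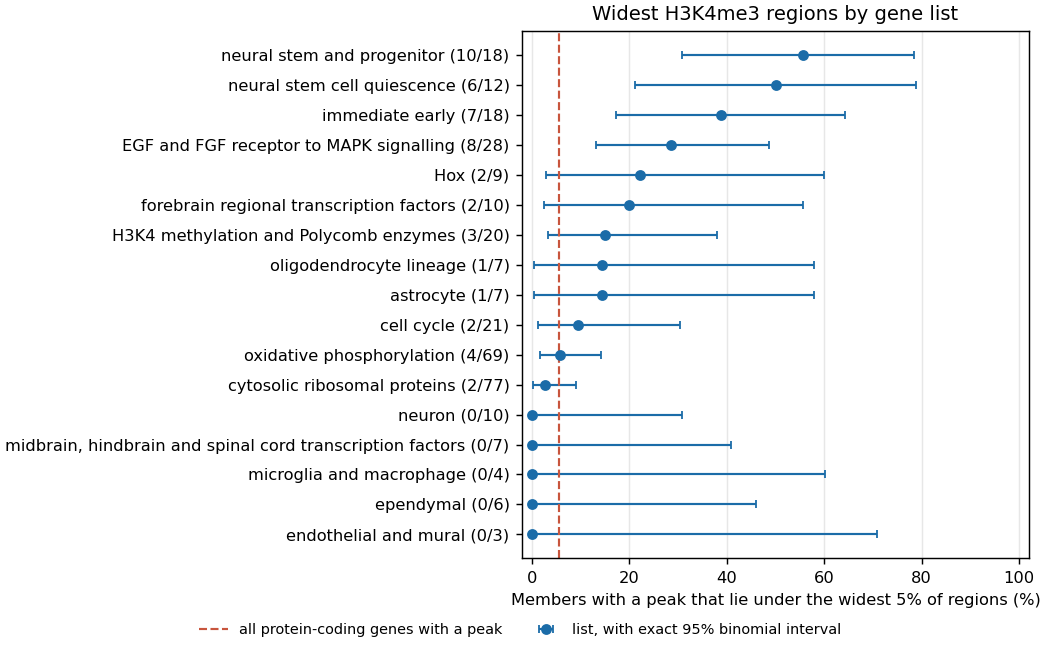
Share of each list's members with a peak that lie under the widest 5% of joined regions (horizontal axis, percent), for lists with at least 3 marked members (vertical axis, with counts). Points carry exact 95% binomial intervals, the dashed line marks the 5.62% of all marked coding genes, and progenitor genes stand highest at 55.6%.

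Away from gene ends the mark was weaker but not absent. Distal peaks, over 5 kb from every annotated gene end, numbered 4556 or 23.7% of peaks (95% interval 23.1 to 24.3), against 73.0% with random placements, and held 8.87% of the tags in peaks. Of these, 67.5% lay over a gene. A minority of the distal peaks, 434 of 4556, had a fold enrichment of 30 or more, as did 8274 of the 12552 peaks at gene ends. The strongest lay between genes on chromosome 6 (128759933 to 128761630, fold enrichment 67.3), 16.9 kb from the nearest gene end, at Klrb1c. The next lay inside Iqgap1, a scaffold protein gene (chromosome 7, 80801473 to 80804079, fold enrichment 65.8), and inside Tnrc6a (chromosome 7, 123123306 to 123126102, fold enrichment 65.5). The gene table gives no start sites inside genes, so a peak at an internal start site counts as distal here. The distal share was 31.3% beyond 2 kb and 17.1% beyond 10 kb.

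A smaller share of coding genes carried the mark on each sex chromosome than on any autosome. The share of coding genes with a peak at an end was 57.8% over the autosomes, from 45.9% on chromosome 7 to 65.4% on chromosome 18, and 39.5% on X (95% interval 36.4 to 42.7). The autosomal share exceeded the X-linked one by 18.2 percentage points (95% interval 15.1 to 21.4, normal approximation over genes, which are not replicates). Peaks at X-linked coding ends had a median fold enrichment of 23.9, against 36.2 to 39.8 on the autosomes. On Y, 5 of 256 coding genes had a peak. Of these 256 genes, 235 lay in runs of like-named neighbours. Outside such runs, 4 of 21 Y-linked coding genes had a peak (95% interval 5.45% to 41.9%).

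**Figure D4:**
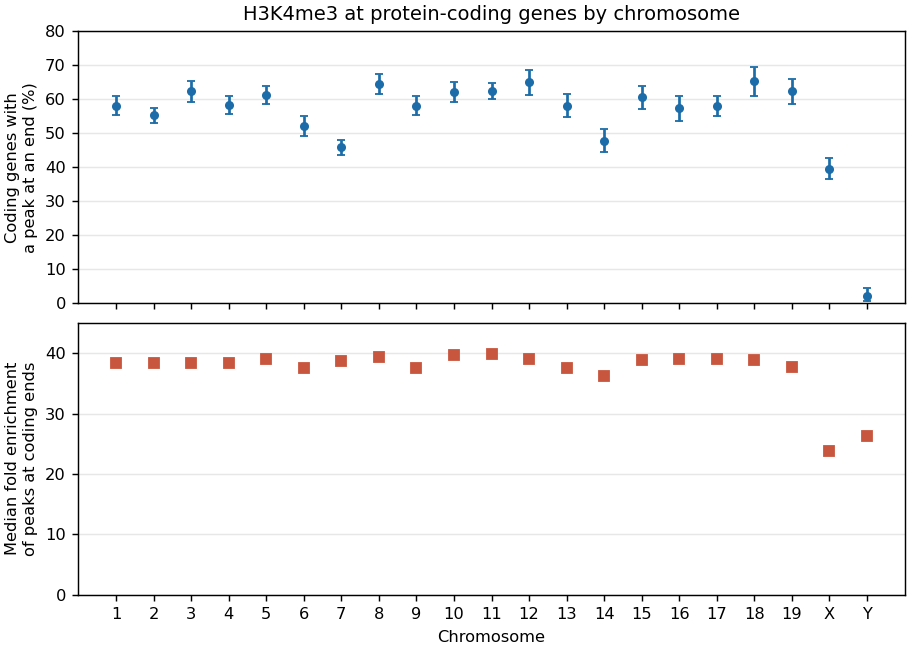
Share of protein-coding genes with a peak at an end (upper panel, percent, with exact 95% binomial intervals) and median fold enrichment of peaks at coding ends (lower panel) for each chromosome (horizontal axis). X stands at 39.5% and a median of 23.9, below every autosome in both panels.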

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

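A signal lay in data that the comparisons did not use: 4 peaks were called above the input on contigs not placed in the assembled chromosomes. Their fold enrichments were 11.6, 32.6, 7.38 and 21.7, with 31, 312, 1863 and 128 tags. The contig peak with 1863 tags had the lowest fold enrichment of the 4. No explanation was tested, since the gene table used here names none of these contigs. With 1 library per kind, no value could be compared with replicates.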

How the results depend on the processing

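Ends of coding genes alone, a peak anywhere over the gene, curated genes, gene density, peaks at 1 coding gene and the removal of runs were chosen after seeing the data. The peak number ranged from 16563 to 19177 under the 3 alternatives. The share of peaks at gene ends, 65.2% as reported, was 72.5% with a -log10 p of at least 10, 62.6% and 70.4% with windows of 500 and 2500 bp, 59.5% with the summit in the window and 58.3% with ends of coding genes alone. The share of coding genes with a peak, 56.3%, was 55.4%, 54.8%, 59.0% and 51.2% under the first 4 of these, 61.5% with a peak anywhere over the gene and 58.1% over curated genes. The distal share, 23.7%, was 31.3% beyond 2 kb, 17.1% beyond 10 kb and 18.2% with a -log10 p of at least 10. The X-linked share, 39.5%, was 49.7% without runs of like-named genes and 43.3% with a peak anywhere over the gene, beside autosomal shares of 67.8% and 63.1%. A fold enrichment of at least 5, which 99.5% of peaks passed, moved none of the shares it was run on out of their intervals. Of the 21 lists, 14 lay outside the central range, against 11 with only peaks at ends of 1 coding gene and 14 or 15 under the other 8 alternatives; of 189 pairs of list and alternative, 9 changed their call and none went from above to below or back. Broad regions set 4 lists apart, and 5 or 6 under the alternatives. Start sites taken as the 5'-most per gene, matching on CpG content and matching on the number of start sites were not run, because the gene table lacks strand, sequence and transcript positions. Depth limits what a missing peak means, since the weakest listed peak held 13 tags. No paired analysis was possible because there is 1 H3K4me3 library, and for the same reason none could be left out.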

Other observations

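The gene families and regions named here, the test on X-linked partner genes and both tests on the Hox clusters were chosen after the values they rest on were seen. The 2 widest regions of all overlapped microRNA genes, along with long non-coding RNA and other genes. Mir9-2 lay under a region of 27.4 kb (mm10 chromosome 13, 83714586 to 83742007), Mir9-1 under 26.0 kb (chromosome 3, 88199897 to 88225896) and Mir9-3 under 20.6 kb (chromosome 7, 79495994 to 79516619), so that the 3 genes of miR-9, a brain-enriched microRNA, ranked 1, 2 and 7 among 18264 regions. As single peaks, without joining, they ranked 1, 6 and 4 by length. The region ranked 5, of 24.1 kb with 3808 tags (chromosome 15, 85664105 to 85688209), overlapped no gene of the table; the nearest gene end, of Lncppara, was 15.6 kb away. All 4 POU class 3 genes lay in broad regions, and so did 6 of the 14 Sox genes looked at (Sox2, Sox4, Sox8, Sox9, Sox11 and Sox21), of which 12 had a peak at an end.

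Other gene families differed in the share of members with a peak at an end, beside 56.3% of all coding genes; no test was run between families. All 10 Frizzled receptor genes, 20 of 22 ephrin and Eph receptor genes, 23 of 29 semaphorin and plexin genes and 12 of 19 Wnt genes had a peak at an end. Of 67 clustered histone genes 59 did, as did 32 of 33 tRNA synthetase genes and 320 of 394 Zfp zinc finger genes (81.2%). Of the clustered histone genes, 15 lay in broad regions. Voltage-gated and other Kcn potassium channel genes had a peak in 39 of 80, glutamate receptor genes in 17 of 26, solute carrier genes in 195 of 337, clustered protocadherin genes in 31 of 57, GABA-A receptor subunit genes in 8 of 19, interleukin genes in 8 of 37 and chemokine genes in 7 of 31. Of 353 vomeronasal receptor genes 1 had a peak, and of 56 keratin-associated protein genes none. At tRNA genes, 143 peaks had a median fold enrichment of 34.8; 98 of these lay at no coding gene end, with a median of 33.9, so that 165 of 408 tRNA genes (40.4%) were marked apart from coding genes.

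Of the 11 HoxA genes 8 had a peak at an end, against 1 of 28 in the other clusters, Hoxc6. A few peaks counted for several close neighbours might give such a pattern, but the HoxA span of 106 kb on chromosome 6 held 9 separate peaks, while the HoxB and HoxD spans held none and HoxC 1. Weak peaks near the calling threshold were also argued against: the HoxA peaks had a median fold enrichment of 29.3, and 7 of the 9 lay above the lower quartile of all peaks, whereas the HoxC peak stood at 9.40. No biological explanation was tested, as the labels give no group to set against it.

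Fewer X-linked than autosomal coding genes had a peak. Runs of like-named neighbours, such as receptor clusters, were a candidate explanation, but without them the autosomal share still exceeded the X-linked one by 18.02 percentage points (95% interval 14.4 to 21.7), at 67.8% against 49.7%. A lower signal per X-linked gene as the whole cause was set against the margin of autosomal genes over the threshold. A -log10 p of at least 20, in place of the p cutoff of 1e-05, stood in for the loss. The autosomal share was then still 55.2%, a fall of 2.56 points, which argues against a loss of the size that this threshold stands for. A stricter threshold on autosomal peaks does not reproduce fewer tags against the background on X, so a larger loss was not tested. A loss of detection over X for another reason, such as tags that cannot be placed, stays open: the X-linked share of 49.7% without such runs is what any other cause would leave too. The gene content of X outside such runs was not tested and stays open as well.

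On Y, Kdm5d, Eif2s3y, Uty, Ddx3y and the predicted gene Gm52481 had a peak, and Xist, the RNA gene of the inactive X chromosome, had none. A hypothesis is that the culture came from male animals. The test took it to need a lower fold enrichment on X. The median at X-linked coding ends, 23.9, lay below every autosome (36.2 to 39.8), 0.618 times the median of autosomes. With 1 X chromosome, however, the input from X would be lower as well. Whether the ratio to the input then falls depends on the background used for each peak, which the peak list does not give. An inactive X chromosome could also lower the median on X, so the fold alone does not separate the sexes. Tags of X-linked partner genes placed on Y could also give Y-linked peaks. These peaks held 0.460, 0.744, 0.564 and 0.368 times the tags of the peaks at Ddx3x, Eif2s3x, Kdm5c and Kdm6a, a median of 0.512. All 4 ratios lay above the 0.2 that the test took this explanation to need, and the median lay just past the 0.5 set against it. The explanation was left open by a stricter rule, set after the ratios were seen, that asks each ratio to reach 0.5, which Ddx3y and Uty did not.

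The score was exactly 3100 in 3926 peaks (20.4%), so it does not rank the strongest peaks. The false discovery rate was 0% in 301 peaks, all with a score above 3100, and reached 0.32% in peaks with a score near 50. Between these it did not follow the score throughout, with a median of 0.02% in the 4469 peaks with a score of at least 3000 and of 0.01% in the 3933 peaks with a score of 200 to 1000.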
